A study of Gallus gallus with 8 samples.

How the data were processed

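Gene expression was measured on Agilent 2-colour microarrays in the livers of 8 chicken (Gallus gallus) embryos, 4 given DEN and 4 given NDELA. Per the labels, total RNA was amplified and labelled with Cy3 or Cy5, and 2 livers given the same compound shared each array, one in each dye. Replicates 1 and 3 of each group carried Cy3, and replicates 2 and 4 carried Cy5. The 4 arrays lay on 2 slides, 1 slide per compound, so slide and compound cannot be told apart. Each sample was the liver of a separate egg, per the labels. No untreated or vehicle-injected embryo was analysed here.

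The arrays were read with Agilent Feature Extraction, per the submitters' processing notes, which give no version. The values the authors deposited are spot intensities on a linear scale, 1 per sample and array spot (feature), each divided by the median of that sample, so that each column has a median of 1. This unit was inferred from the values: all values of a sample were whole multiples, within 0.01, of 1 over a whole number between 460 and 1028. That number is the sample's median in scanner units. Whether a local background was subtracted, and by which rule spots were emptied, is not given in the sources used here. The table held 45220 features, of which 1417 were empty in all samples, and 43803 had a value in at least 1 sample. The low end of each column did not reach 0: the 1st percentile lay at 65 to 81 scanner units in Cy5 and at 157 to 213 in Cy3. In Cy3 it was lower in DEN (162 and 157) than in NDELA (213 and 209). In Cy5 it was higher in DEN (81 and 80) than in NDELA (66 and 65). No background or saturation call accompanied the values, so it is not known which features were above background, and where background remains in the values, a ratio of 2 intensities understates the change of a dim feature. The number of arrays limits the precision.

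Rows of the table carry a feature number and no probe name, gene or coordinate, and no table linking these numbers to genes was used here. Results are therefore given by feature, spots of 1 probe or gene were not averaged, and no genomic position is given. The 40 gene lists fixed before the data were examined (damage response, repair, xenobiotic and alcohol metabolism, stress, liver functions, cell type markers and W-linked genes) could not be matched to features and were not tested. The same holds for the single genes chosen beforehand and for the check of sex-linked genes. The rule for named genes asked for called genes with a symbol and the largest differences in each direction, with a mean level above the 25th percentile and no overlap between the groups, followed by the smallest p where too few were called. It was written for 12 named genes a direction and was applied, without the symbol, to 2 features a direction, because a feature number alone tells little.

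Values were turned into log2, the 34366 features with a value in every sample were kept, and each sample was centred on its median over those features. Each feature was tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3). The model held the compound and the dye as fixed effects and the array as a random block (duplicateCorrelation, statmod 1.5.0). The dye term follows the series' design, in which samples with the same dye were compared and the results averaged. Differences are DEN minus NDELA, and a feature was called at a Benjamini-Hochberg adjusted p below 0.05. The dependence on dye was tested as the interaction of dye and compound in the same fit. Tested on simulated data with the spread of these samples, over the same 34366 features, the comparison of DEN with NDELA called 64.2% of 67 features made to differ by 1 on the log2 scale. It called 95.5% of 67 features that differed by 2 and 97% of 66 that differed by 4, with 16 false calls among the unchanged features. All of these features differed in the same simulated set, and the adjusted p depends on how many features differ. The shares therefore apply to data with that many differences and are not the power of the real comparison. Molar amounts of the compounds were computed with rdkit from their structures.

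Alternatives chosen before the data were examined changed the array block, the dye term, the centring, the filter on dim features, the prior of the variances, the pseudocount, the handling of empty values, the threshold and the samples included. Those added afterwards were a background correction (normexp, offset 50), the brighter 50% of features, cyclic loess without the dimmest 25%, and an adjusted p below 0.1.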

Results

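Livers of 8 White Leghorn chicken embryos were profiled on the 11th day of incubation. Of their eggs, 4 had been injected with N-nitrosodiethylamine (DEN) and 4 with N-nitrosodiethanolamine (NDELA), a pair of related nitrosamines in which NDELA carries a hydroxyl group at the end of each ethyl arm of DEN. Both were given as 4 mg in 0.15 ml of water per egg, and days 9, 10 and 11 of incubation are named as injection days for DEN. The wording does not repeat the days for NDELA, nor say whether 4 mg was the amount of each injection or the total. The same mass held more DEN than NDELA, 39.2 against 29.8 micromol, so the doses matched by mass and not by molar amount. The embryos were of undetermined sex. The series addressed the genotoxicity of nitrosamines, and the comparison its design implies is DEN against NDELA, between samples that carried the same dye. The table numbers its array spots (features) and pairs none with a gene, so the account is by feature, with 2 numbered in each direction.

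The median listed spot was brighter in the livers given DEN. In Cy3 it stood at 615 and 529 scanner units in DEN replicates 1 and 3, against 460 and 474 in NDELA replicates 1 and 3. In Cy5 it stood at 1028 and 839 in DEN replicates 2 and 4, against 630 and 671 in NDELA replicates 2 and 4. More features were left empty in the Cy5 samples of DEN (6460 and 7190) than in those of NDELA (4326 and 4456), while no Cy3 sample lacked more than 198. The 9437 features listed in some samples only were dim, with a median Cy3 level of -1.10 on the log2 scale relative to the sample median, against 0.72 for the 34366 features listed in every sample. Of the emptied values among them, 98.2% were in Cy5. Both Cy5 samples of DEN were empty, and both Cy5 samples of NDELA listed, at 1102 features, and the opposite held at 85. Emptying more dim spots raises the median of those left, so part of the Cy5 difference in the median spot may come from it.

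The 8 liver profiles resembled each other, with Pearson correlations across features of 0.942 to 0.986 between samples. Dye accounted for 52.9% of the variation of log2 levels, compound together with slide for 15.8%, array within compound for 16.6% and the rest for 14.8%. No pair of samples held identical values. The median SD of a feature between replicates, after adjustment for dye, was 0.199 in DEN and 0.175 in NDELA on the log2 scale (n = 4 each), a ratio of 1.14. This ratio has no test and fell to 0.94 without DEN replicate 2 and to 0.98 without DEN replicate 4.

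Of the 34366 features, 4 differed between DEN and NDELA at an adjusted p below 0.05 in limma, 3 of them higher and 1 lower in DEN. The strongest differences were a pair of features about 50 times brighter after DEN. Feature 12643 had an intensity of 70.8 ± 27.8 times the sample median (SD, n = 4) in DEN and 1.26 ± 0.185 (SD, n = 4) in NDELA. Its fold was 54.0, with a 95% interval of 31.5 to 92.3 (log2 difference 5.75, SE 0.34, limma adjusted p = 0.00506). Feature 37801 had an intensity of 52.6 ± 21.5 times the sample median (SD, n = 4) in DEN and 0.981 ± 0.185 (SD, n = 4) in NDELA, a fold of 50.9 with a 95% interval of 28.3 to 91.5 (limma adjusted p = 0.00557). In both features DEN replicate 2 was the lowest of the DEN livers, at 37.0 and 22.8 times the median, and still lay far above every NDELA liver, of which the highest stood at 1.52 and 1.20. The remaining called feature, not numbered here, was 4.74 times brighter in DEN, at 3.52 ± 1.86 against 0.700 ± 0.225 times the median (SD, n = 4 each; limma adjusted p = 0.00568).

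Feature 44994 was dimmer after DEN. It stood at 3.21 ± 0.995 times the sample median (SD, n = 4) in DEN and at 19.8 ± 4.28 (SD, n = 4) in NDELA, a 6.12-fold difference with a 95% interval of 4.41 to 8.48 (log2 difference -2.61, SE 0.20, limma adjusted p = 0.0119). Next in that direction, feature 14569 had a mean of 28.6 ± 4.43 times the median (SD, n = 4) in DEN and 66.7 ± 6.97 (SD, n = 4) in NDELA, with all 4 DEN livers below all 4 NDELA livers, and did not pass the threshold (log2 difference -1.20, 95% interval -1.49 to -0.91, limma adjusted p = 0.0567). In each of the 4 called features the Cy3 and the Cy5 samples differed in the same direction. So did 100% of the 8679 features at an unadjusted p below 0.05 in limma, so this agreement is not particular to the 4. The differences were 5.52 in Cy3 and 5.99 in Cy5 for feature 12643, 5.56 and 5.78 for feature 37801, and -2.59 and -2.64 for feature 44994.

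**Figure D1:**
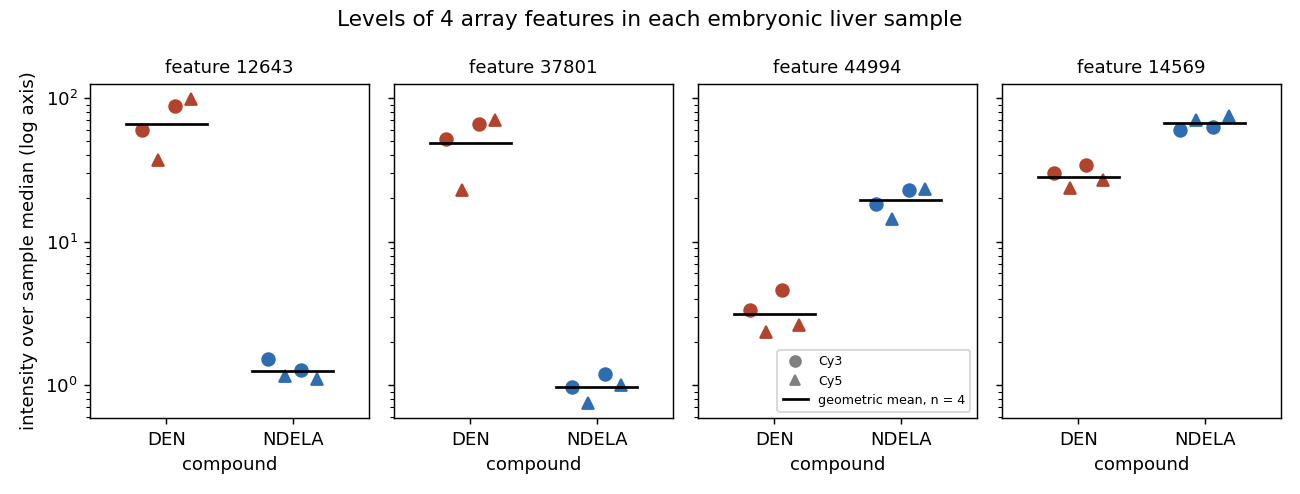
Intensity of 4 array features over the sample median (vertical axis, logarithmic, no unit) in each liver, by compound. Circles are Cy3 samples, triangles Cy5 samples and lines the geometric mean of 4 samples. For features 12643 and 37801 the DEN samples lie between 22.8 and 98.6 and the NDELA samples between 0.752 and 1.52, and for features 44994 and 14569 the DEN samples lie below the NDELA samples.

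The number of called features was sensitive to the samples and the model. It fell to 0 without NDELA replicate 3 (5939 features at an unadjusted p below 0.05 in limma) and to 1 without NDELA replicate 1, and rose to 18 without DEN replicate 2. Leaving out a whole array gave 2956 calls without DEN replicates 3 and 4, 88 without DEN replicates 1 and 2, and 1 without NDELA replicates 3 and 4. That 1 call, and the 3 calls without NDELA replicates 1 and 2, included 0 of the 4. With no array block there were 3625 calls, and with the arrays averaged, 2 against 2, limma called 0 features, with 6451 at an unadjusted p below 0.05. The share of calls higher in DEN was 75.0% of 4, against 26.9% of 108 after quantile normalization and 23.4% of 47 after cyclic loess. It was also 26.4% of 3706 calls at an adjusted p below 0.1 without either scaling. The direction of all 5 features described above was the same under every alternative in which they were tested. The groups did not overlap at any of the 5, so leaving out samples, an array or a dye could not reverse that direction.

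At an unadjusted p below 0.05 in limma there were 8679 features (25.3% of those tested), 2739 higher and 5940 lower in DEN, against 5753 after quantile normalization and 5517 after cyclic loess. Splits of the 8 samples other than DEN against NDELA gave up to 5659, and those that kept each array whole gave up to 610. The groups did not overlap at 2599 features (7.56%), 1336 higher and 1263 lower in DEN. Chance gives 2.86% for samples that share no dye or array, which these do. The groups of the other splits that kept each array whole did not overlap at 730 (2.12%) and 288 (0.838%) features. Splits across arrays reached 1489 (4.33%) where the dyes were balanced between the groups, as in the real split. They reached 2371 (6.90%) where both dyes were in each group in unequal numbers, so that dye adds to the count. A difference of 2-fold or more was estimated for 549 features, 277 higher and 272 lower in DEN. The 95% interval had a median half-width of 0.41 on the log2 scale. For 27488 features (80%) it lay within 2-fold in either direction, and for 11034 (32.1%) within 1.5-fold. For these features a larger difference of intensity between the groups lay outside the interval. The groups differed in slide as well as compound, and background left in the values would understate a change of a dim feature.

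The direction of the difference followed the level of the feature. With the features ordered by mean level and cut into 10 equal groups (deciles), 95.2% of the dimmest decile were lower in DEN, with a median log2 difference of -0.37, and 39.2% reached an unadjusted p below 0.05. In decile 9, 26.4% were lower in DEN, with a median of 0.17. The shift of the dimmest decile was -0.66 and -0.42 in the Cy3 pairs of samples (numbers 1 and 3), and -0.33 and -0.07 in the Cy5 pairs (numbers 2 and 4). The numbers name the samples, and other pairings within a dye lay between -0.53 and -0.12. The called features lay in deciles 5, 8 and 9.

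**Figure D2:**
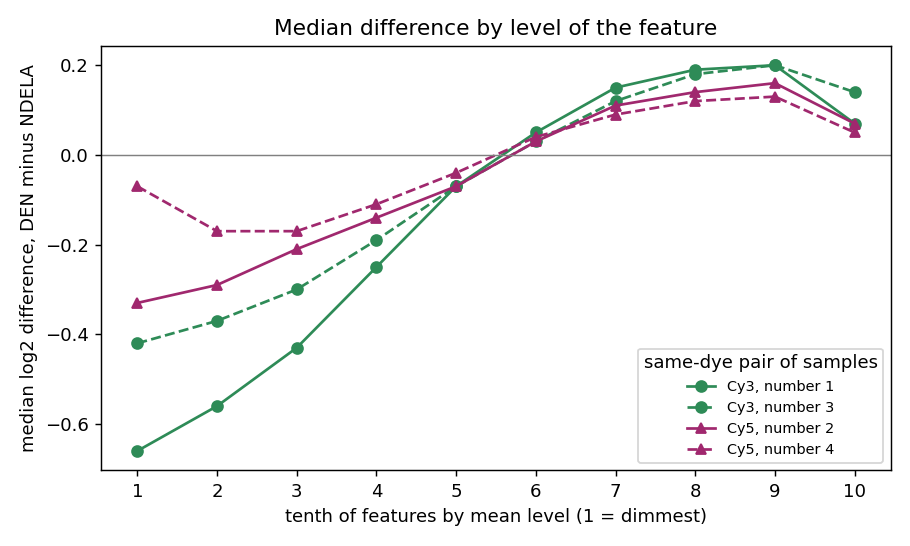
Median log2 difference between DEN and NDELA samples of the same dye and number (vertical axis) by decile of mean feature level (horizontal axis, 1 is the dimmest), with 1 line per pair of samples, green for Cy3 and magenta for Cy5. All 4 pairs lie below 0 in the dimmest decile, from -0.66 to -0.07, and above 0 from decile 6 on.

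The comparison was then made in each dye. The difference had the same sign in Cy3 and in Cy5 at 72.4% of the features, with a correlation across features of 0.51 (features are not independent replicates). The other splits that kept each array whole gave 65.9% and 62.0% (exact permutation test over 3 splits, one-sided p = 0.33, the smallest they allow). No feature showed an interaction of dye and compound in limma (0 called, smallest adjusted p = 0.546), and 2680 (7.80%) had an unadjusted p below 0.05. Without the array block limma again called 0, with 1335 at an unadjusted p below 0.05.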

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

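In 1 measure a single sample stood apart from the other 3 of its group by Dixon's test. DEN replicate 2 was at least 4-fold above every other sample at 63 features, against 5, 1 and 0 features for the other DEN livers and 2 to 9 for the NDELA livers. Of 24 groups of 4 values examined, this was the 1 that passed. Chance gives about 1.2 for independent groups of normal values, which these are not, since each group mixes both dyes.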

How the results depend on the processing

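In this balanced design, leaving out the array block or the dye term, or averaging the arrays, cannot change the difference of a feature. The count of 4 called features moved with these and with other choices. It was 3625 with no array block, 370 with no dye term, 0 with the arrays averaged (limma, 6451 at an unadjusted p below 0.05), 108 after quantile normalization, 47 after cyclic loess, 7 without centring, 135 with a pseudocount of 0.134, 2 in the Cy3 samples alone and 2 in the Cy5 samples alone, the latter not among the 4. At an unadjusted p below 0.05 with a 1.5-fold difference it was 3115. Chosen after seeing the data, an adjusted p below 0.1 gave 3706, and cyclic loess without the dimmest 25% gave 157. Normexp and the brighter features alone, also chosen then, gave 4 and 6. The replicate block, with the number in place of the dye, gave 2058 calls. Dye-adjusted deviations of same-numbered samples correlated at -0.27, 0.21, -0.13 and 0.24. These were not set against differently numbered pairs, so whether the numbers pair the embryos is not known. Leaving out 1 sample gave 0 (NDELA replicate 3; limma, 5939 at an unadjusted p below 0.05) to 18 calls (DEN replicate 2), with 1 without NDELA replicate 1. Leaving out the array of DEN replicates 3 and 4 gave 2956, that of DEN replicates 1 and 2 gave 88, that of NDELA replicates 3 and 4 gave 1, and that of NDELA replicates 1 and 2 gave 3; the calls without either NDELA array included 0 of the 4. The cause of these changes was not tested further. Other choices made before the data were examined gave 3 to 5 calls, at least 3 of them among the 4. Feature 12643 passed in 23 of 28 alternatives, with log2 differences of 5.24 to 6.26 and adjusted p of 0.000281 to 0.421. Feature 37801 passed in 22 of 28 and feature 44994 in 19 of 28. Feature 14569, not called, passed in 10 of 28. The ratio of replicate spreads ran from 0.94 to 1.45 when 1 sample was left out, below 1 without DEN replicate 2 (0.94) or DEN replicate 4 (0.98). The share of features with 1 direction in both dyes, 72.4%, was 66.9 to 73.3% without 1 sample. Under scalings added later it was 59.2% without centring, 69.2% after cyclic loess and 70.1% after quantile normalization. Alternatives that needed gene names (choice of probe, sex-linked genes, all gene list tests) were not run. Signal over background could not be assessed, since the values carry no background call.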

Other observations

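The tests in this part were chosen before their result was seen for the array surface around the called features, the slides and the Cy3 background, and after it for the splits of the samples, the Cy5 background, the comparison of dyes in the dimmest features and the dye, array and array partners of the low samples.

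Some features were present in 6 livers and low in 2, in a pattern that cut across the compounds. At 23 features DEN replicate 1 and NDELA replicate 4 lay at least 4-fold below the other 6 livers. The median log2 level of these features was -0.70 and -0.72 in those 2, and 2.69, 3.01, 3.08, 2.63, 3.00 and 2.63 in DEN replicates 2, 3 and 4 and NDELA replicates 1, 2 and 3. At 15 other features DEN replicate 2 and NDELA replicate 1 were the low livers, at 0.15 and -0.21, with the other 6 between 2.82 and 4.49. Of the 28 possible pairs of livers, the next, NDELA replicates 1 and 2, had 4 features low in both, and this pair shared an array. Another 15 features were at least 4-fold higher in DEN replicate 2 and NDELA replicate 2, which both carried Cy5, than in the other 6 livers.

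A difference between the embryos, such as an inherited variant, is a candidate explanation for the 23 and the 15 features, and 1 embryo of each compound was low in each pattern. Sex divides the embryos in 1 way only, and the low livers differed between the patterns, so sex could account for at most 1 of them. In 0 of the patterns of the 23 and the 15 features did the low livers share a dye or an array, which argues against either as the cause of those patterns. A blemish on the array surface would lower both livers on an array. The other liver on the array lay above the low one by a median of at least 3.60 on the log2 scale over the 23 features. Over the 15 the median was at least 3.03. The features were picked for a gap of at least 4-fold to every other liver, array partners included, so these gaps decide nothing about a blemish. Position, on a grid assumed from the feature numbers, argues against a local blemish for the 23 features. Of them, 0 lay within 2 spots of another, and they spread over rows 5 to 500 and columns 6 to 79. All of 10000 random sets of features (100%) had at least as many side by side. For the 15, position did not settle it: 2 lay side by side with another, and 5.27% of random sets had as many. Neither inheritance nor sex, as the source of 1 pattern, could be tested, because 0 columns of the table name a gene or chromosome.

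For the 4 features called between DEN and NDELA, the livers shared arrays in pairs, and 3 splits into 4 and 4 kept each array whole, too few for a share under 0.05: 1, the real one, called 4 features and the highest of the others 0 (over all 34 splits that could be fitted, the highest other called 2). Embryo differences that fell on the groups by chance stay open: 5 features, with 12643 and 37801 among them, were parted by 4-fold or more in the real split and 0 in the others that kept each array whole, of which there are again too few (1 of 3 as large). The other 2 called features were parted by less and lie outside that count. A blemish is argued against by the neighbouring spots, on a grid of 85 columns assumed from the feature numbers, whose median difference was at most 0.059 of that of the called feature. A difference between the slides cannot be told apart from the compound, because 0 slides held both groups.

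The lower level of dim features in DEN may in part come from background left in the values. Subtracting each sample's 1st percentile from the 22190 features at least 2 times above it left 51.0% of the range of the decile medians in Cy3, from 0.51 to 0.26, which leaves this open. In Cy5 114.7% of the range was left, from 0.42 to 0.48, which decides nothing, because the floors of the groups differed by 0.03 there and the dimmest spots were left out. These floors are the 1st percentiles on the centred log2 scale, DEN minus NDELA. In Cy3 they differed by -0.89, beside a median difference of -0.53 in the dimmest decile, which was -0.19 in Cy5. A change of the transcripts alone would shift both dyes alike, were their embryos alike, their backgrounds equal and no features left out. Each dye was carried by different embryos, however, and the 1st percentile was higher in Cy3. Features emptied in any sample were left out as well. Of these, 1102 were empty in both Cy5 samples of DEN and listed in both of NDELA, against 85 the other way. The shift in Cy5 may therefore differ from that in Cy3 under this explanation too. Paired by number, every Cy3 pair lay below every Cy5 pair in the dimmest decile. The gap was 0.09, less than the range of 0.26 within a dye. The pairing crossed in both dyes gave 0.23 against 0.18, so a change of the transcripts alone is open too. The slides also differed between the compounds.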
